A study of soil metagenome with 18 samples.

How the data were processed

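Soil was taken from field plots of 6 fertilization treatments in a paddy, with 3 samples per treatment and 18 in all. Per the labels' protocols, each sample mixed 10 cores of 1.5 cm diameter from the top 15 cm of 1 plot and was passed through a 2 mm mesh. Genomic DNA was extracted by freeze-grinding with SDS and gel purification, and labelled with Cy5 by random priming, again per the labels' protocols. Each DNA was hybridised to 1 GeoChip array in 1 colour, so every value is a single-channel signal with no reference sample on the same slide.

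The deposited table gives 1 intensity per probe and array, on a linear scale, with a gene name, category and organism for each probe and blanks where a probe has no value. The scanner, the image software, the detection rule, the background treatment and the normalization are not given in the sources used here. The values themselves show that the intensities had been multiplied by 1 factor per array. For each array the factor was recovered by searching for the value that turns the listed intensities into multiples of 0.01, within 0.1 of such a step. On each array the recovered factor did so for at least 89.1% of the values. The search covered only factors that put the highest unscaled value near 65535, taken as the scanner limit. That this value lay between 64273 and 64928 is therefore no check on the factor. The recovered factors ran from 1.42 to 6.31. How the factor was chosen for each array is not given in the sources used here, and neither are slides or scanning days.

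The table held 56043 probes, of which 1507 had a value on no array and 17971 on all 18 arrays, and 991 had no organism. A probe with a value was taken as detected. Probes detected in at least 2 of the 3 replicates of at least 1 treatment were kept, 49336 in all. Arrays were scaled to each other by the median log2 ratio to the mean over the probes detected on all 18 arrays. Blanks and values under a floor of 1126, the 1st percentile of scaled values, were set to the floor for probe tests. The value of a gene family was log2 of the sum of its scaled signals plus the floor, for the 416 gene names with at least 3 kept probes. A gene name pools probes of many organisms, so a family value is a sum over organisms and can be carried by its brightest probes.

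Detected probes and the Shannon index were compared across the 6 treatments by the share of variance between treatments, with 100000 random regroupings, and between pairs of treatments with two-sided exact permutation tests, whose smallest p at 3 against 3 is 0.1. Composition was compared by PERMANOVA on Bray-Curtis dissimilarities of scaled signals with adonis2 of vegan, whose permutations give a p of 1e-04 at the lowest. Families were tested with limma in 1 model with a mean for each treatment and 12 residual degrees of freedom, in 10 comparisons: each fertilized treatment against Control, the steps NR against R, NPR against NR, NPKR against NPR and L_NPKR against NPKR, and the mean of the treatments with phosphorus against the mean of those without. Probes were tested in the same way, and are reported for 6 comparisons. The p-values were adjusted by the Benjamini-Hochberg method within each comparison, and families or probes with an adjusted p under 0.05 were called. The p-values measure the spread between plot samples of a treatment, and do not carry errors shared by all arrays of a treatment.

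Gene families were named by a rule: against Control and in the phosphorus contrast, up to 8 higher and 8 lower called families with the largest change and at least 5 kept probes; in the 4 steps, up to 5 each way; and the 4 families with the smallest p where fewer than 4 passed. Key families of nutrient cycling and up to 4 examples per fixed list were also named. Up to 3 probes each way were named for each comparison with Control, among called probes detected on all arrays of both treatments. The tests, the rule, the lists and all alternatives except those named as chosen later were set before the data were examined.

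There were 31 fixed lists of gene names, which matched 144 families. Lists with at least 3 families, 21 in all, were tested with camera in limma at a preset correlation of 0.01, with camera at an estimated correlation and with fry, and the p-values were adjusted over the 21 lists within each comparison, which makes 210 tests in all. For each list the number of called families was also counted with p-values adjusted over the list alone.

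The limma tests were tested on simulated data, made by drawing values with the real means, spreads and group sizes and adding known changes. For families in NPKR against Control, 76.7% of 30 families changed by 0.5 (log2) and 20% of 30 changed by 0.25 were called, with 2 false calls among 31. In NPR against NR the shares were 80% and 56.7%, and in R against Control 90% and 26.7%. For probes in NPKR against Control, 7% of 100 probes changed by 1 and 0% of those changed by 0.5 were called; in the phosphorus contrast the shares were 40% and 11%. Most simulated probe changes of 1 were therefore missed. The simulation changed few of the 49336 probes, which makes the adjusted threshold stricter than with many changed probes. Its values were drawn independently, without errors shared by an array. These shares and false calls need not hold for the data, where 7250 probes were called in NPKR against Control.

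The alternatives were total-signal scaling, quantile normalization and no scaling between arrays; stricter and looser probe filters; a floor at the 5th percentile; a family value that is the mean of log2 values; families with at least 1 kept probe; the replicate number as a block; eBayes with trend and robust settings; a model with the compared treatments alone; other dissimilarities; and each array left out in turn. A floor matched to the dimmest array, 2107, below which every array was set to undetected, log2 of the scaling factor as a covariate, and total-signal scaling for the lists, with either correlation, were chosen after seeing the data. Cross-hybridisation between related genes, dye and spot effects and the amount of DNA per gram of soil were not measured in the table, and soil chemistry and crop yield were not analysed here. The work used R 4.3.3, limma 3.58.1, vegan 2.7.1, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9, with random seed 1.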

Results

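The series profiled microbial functional genes in a paddy soil kept under long-term fertilization. Soil DNA was labelled with the dye Cy5 and hybridised to GeoChip arrays, whose probes target microbial genes of nutrient cycling, stress response, resistance and contaminant breakdown. There were 6 treatments with 3 arrays each: an unfertilized control (Control), straw of rice alone (R), straw with nitrogen (NR), straw with nitrogen and phosphorus (NPR), straw with nitrogen, phosphorus and potassium (NPKR), and a treatment in which both the straw and the 3 nutrients were applied at reduced rates (L_NPKR). The signal of a probe was read as the relative amount of matching DNA within the labelled DNA, not as an amount per gram of soil. It carries no information on transcription. The table held 56043 probes under 493 gene names in 13 categories, of which 416 gene families were tested. Between 30408 and 46414 probes had a listed intensity on an array, and the listed intensities of an array, in units of 1e+06, summed to a mean of 317 in NPR, the lowest, and 416 in NPKR, the highest. With 3 arrays per treatment, the number of arrays limits the precision of each comparison.

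More functional gene probes were detected in every treatment that received nitrogen than in Control or R. Control arrays detected 35064 ± 1430 probes (SD, n = 3) and R arrays 31903 ± 2028. The means were 40803 ± 1747 in NR, 39730 ± 798 in NPR, 44349 ± 1333 in NPKR and 45302 ± 963 in L_NPKR, and no array of these treatments fell within the range of Control or R. Against Control these means were higher by 16.4%, 13.3%, 26.5% and 29.2%, while R differed by -9.02%. The Shannon index of the probe signals followed the same order of treatments, from 9.91 ± 0.052 in R and 9.99 ± 0.029 in Control to 10.2 ± 0.023 in NPKR and 10.2 ± 0.013 in L_NPKR. Treatments held 94.2% of the variance of detected probes and 94.4% of that of the Shannon index, with a permutation p of 1e-05 each, the smallest that 100000 resamples can give. In two-sided exact permutation tests of 3 arrays against 3, detected probes and the Shannon index gave p = 0.1 for NR, NPR, NPKR and L_NPKR against Control, the smallest p this design allows. R against Control gave an exact p of 0.2, NPR against NR gave 0.4, and L_NPKR against NPKR gave 0.4 for detected probes and 0.2 for the Shannon index. Over the 9 comparisons made, the Benjamini-Hochberg adjusted exact p was 0.15 at its lowest.

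The brightness of the arrays also differed between treatments. The listed intensities were multiples of a scanner signal, and the factor recovered from them was 4.10 ± 0.416 in Control, 5.23 ± 1.41 in R, 2.03 ± 0.058 in NR, 2.57 ± 0.429 in NPR, 1.84 ± 0.102 in NPKR and 1.64 ± 0.234 in L_NPKR (SD, n = 3). Treatments held 91.2% of the variance of its log2. A high factor was taken to mark a dim array, and the treatments with the most detected probes had the lowest factors. The median signal of an array divided by its factor was 1708 ± 128 in Control, 1476 ± 253 in R and 2654 ± 92.7 in NR. It was 1949 ± 341 in NPR, 2969 ± 51.1 in NPKR and 3043 ± 359 in L_NPKR. By that measure NPR overlapped Control: NPR replicate 3 was at 1653, and Control ran from 1563 to 1807. With 1 signal floor applied to every array, the means were 32855 ± 956 probes in Control, 31043 ± 1286 in R, 38106 ± 510 in NPKR and 38297 ± 68.5 in L_NPKR, and treatments held 94.3% of the variance (permutation p = 1e-05). The excess of NPKR over Control was 5251 probes with that floor and 9284 without it. NR and L_NPKR then exceeded Control by 11.1% and 16.6%.

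**Figure D1:**
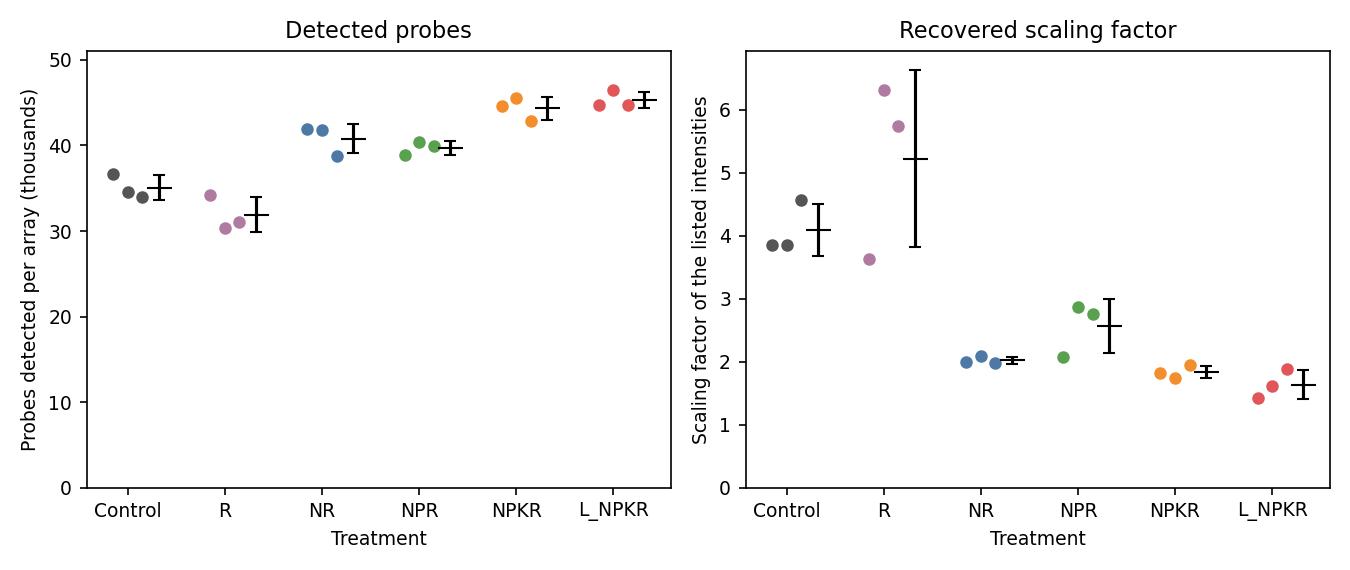
Probes detected per array in units of 1000 (left) and the recovered scaling factor of the listed intensities (right) for each of the 6 treatments, with a dot per array and a black mark for the mean ± SD of 3 arrays. Detected probes ran from a mean of 31903 in R to 45302 in L_NPKR, while the factor ran from 5.23 down to 1.64 in the same treatments.

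The composition of the functional genes differed between treatments. In a permutation test on Bray-Curtis dissimilarities (adonis2), the treatments accounted for 56.0% of the variation (pseudo-F = 3.05, permutation p = 1e-04, the smallest these permutations can give). Arrays of one treatment differed by a mean dissimilarity of 0.164 over 18 pairs, and arrays of different treatments by 0.210 over 135 pairs. The closest treatments compared were L_NPKR and NPKR, at 0.157, and NPR and NR, at 0.176. NR and R lay at 0.256, L_NPKR and Control at 0.242, and NPKR and Control at 0.238. Arrays within R differed by a mean of 0.207, more than R and Control at 0.190. Whether the treatments differ in their spread was not tested. Undetected probes counted as 0, so the dissimilarities also carry the differences in detected probes, and with them those in array brightness.

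**Figure D2:**
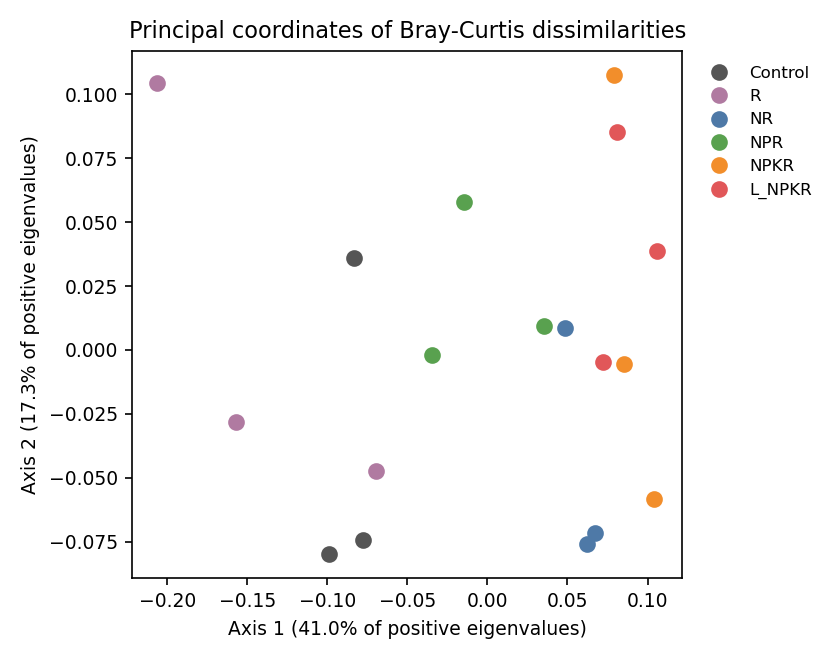
Principal coordinates of the Bray-Curtis dissimilarities between the 18 arrays, with axis 1 (41.0%) on the horizontal and axis 2 (17.3%) on the vertical and a dot per array coloured by treatment. Every array of Control and R lay below 0 on axis 1, every array of NR, NPKR and L_NPKR lay above 0, and the NPR arrays ran from -0.0345 to 0.0353.

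Gene families were compared on the log2 scale with limma, and each change below is a log2 difference with its standard error and the Benjamini-Hochberg adjusted p within the comparison. Undetected probes counted as 0 in the family sums, so a family can also rise where more of its probes were detected. The direction of many small changes depended on how arrays were scaled to each other. With the median scaling used throughout, the median family shifted by 0.11 in NR, 0.06 in NPR, 0.21 in NPKR and 0.16 in L_NPKR against Control, and by 0.15 in NPKR against NPR. With total-signal scaling these shifts were 0.0013, 0.016, 0.019, 0.018 and 0.0041. The change of a family that was rarely detected in Control depends on the floor added to its sum: integrase_serine had a mean of 2.72 in Control (units of 1000), which includes the floor of 1126, so its size and rank are not exact. Relative to the median family, the values of main key families are given with those comparisons whose median shifted by over 0.1; the shift was 0.125 in NR against R and 0.105 in the phosphorus contrast. With log2 of each array's scaling factor added to the model, which was chosen after seeing the data, limma called 0 families in R, NR, NPR, NPKR and L_NPKR against Control, with 24, 25, 41, 68 and 47 at an unadjusted p under 0.05. It called 2 in NR against R and 1 in NPKR against NPR. Since the factor differs mostly between treatments, this model can also remove real differences.

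**Figure D3:**
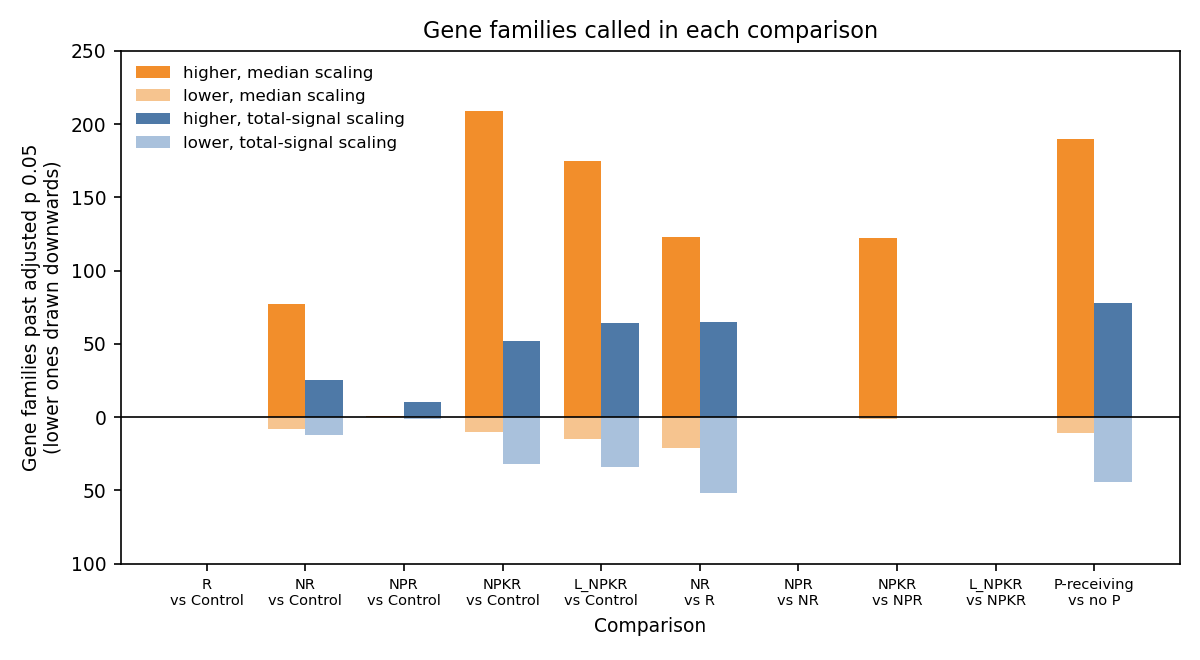
Number of the 416 gene families past an adjusted p of 0.05 in each comparison, with families of higher signal in the group named first drawn upwards and those of lower signal downwards, for median scaling and total-signal scaling. In NPKR against Control 209 families were higher and 10 lower with median scaling, and 52 and 32 with total-signal scaling.

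Straw alone was compared with Control. The methanogenesis family mcrA, which encodes methyl-coenzyme M reductase, differed by -0.10 ± 0.078, and nirS, the cytochrome cd1 nitrite reductase of denitrification, by -0.14 ± 0.052 (adjusted p 0.485). The families with the smallest p were msmABCD at -0.73 ± 0.205, 4Fe_4S_ferredoxin at 0.36 ± 0.11, pectinase at -0.23 ± 0.067 and cda at 0.17 ± 0.038, with adjusted p of 0.287 for cda and 0.452 for each of the others. None of the 416 families passed the limma test, and 40 had an unadjusted p under 0.05. Total-signal scaling also gave 0, with 44 at an unadjusted p under 0.05, and quantile normalization gave 2. Among single probes 157 passed, 27 higher and 130 lower, but 0 of those detected on all 18 arrays passed in limma (1700 at an unadjusted p under 0.05), and 38 passed with the matched floor and 38 with only the compared groups in the fit. With all kept probes, a HcaB probe of Rhodococcus rose by 0.84 ± 0.15, and a SilA probe of Bradyrhizobium, from a silver efflux system, fell by 1.43 ± 0.27. Without R replicate 1, 5 families and 1557 probes passed, and 1 family passed without R replicate 2 and 1 without R replicate 3. R replicate 1 detected 34211 probes, within the range of Control (33942 to 36674), and had a factor of 3.63. R replicates 2 and 3 detected 30408 and 31089 probes, with factors of 6.31 and 5.74. The probe count was 270 without Control replicate 1 and 239 without R replicate 3.

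Nitrogen with straw was next set against Control. The mcrA signal rose from 607 ± 17.4 in Control to 823 ± 52.4 in NR (mean summed signal in units of 1000, SD, n = 3), a change of 0.44 ± 0.078 (limma adjusted p = 0.00438) and 0.33 above the median family. The methane oxidation gene pmoA rose by 0.325 ± 0.052, nirS by 0.30 ± 0.052, the nitrous oxide reductase gene nosZ by 0.29 ± 0.080, the glutamate dehydrogenase gene gdh by 0.33 ± 0.099, the polyphosphate kinase gene ppk by 0.28 ± 0.065 and pectinase, which breaks down plant cell walls, by 0.48 ± 0.067. Relative to the median family these 6 were at 0.21, 0.19, 0.18, 0.22, 0.17 and 0.37, and with total-signal scaling nosZ and gdh no longer passed (adjusted p = 0.0631 and 0.0952). When only probes detected on all 18 arrays were kept, nirS, nosZ and gdh were at 0.10, 0.17 and 0.20 and did not pass (adjusted p = 0.156, 0.0702 and 0.126). Among families with at least 5 kept probes, the phage family integrase_serine, an enzyme that inserts phage DNA into host genomes, rose by 2.18 ± 0.39 (adjusted p = 0.00438), and its probes were detected in 14 of 15 measurements in NR and 3 of 15 in Control. It was followed by arsenic_resistance_gene at 1.02, the phage family helicase_family_4 at 0.94, the aromatic degradation families phdG at 0.81 and phdJ at 0.70 (adjusted p = 0.0855 with total-signal scaling), arcA at 0.585, nicdehydr at 0.58 and mhqA at 0.57. The lower families of that size were thioredoxin, which fell by 0.51, the contaminant degradation family arhA, which fell by 0.32, and arcB, the sensor kinase that pairs with the oxygen-limitation regulator arcA, which fell by 0.23 with all kept probes but was at -0.01 over its probes detected on all 18 arrays (adjusted p = 0.956). Of the denitrification list, 3 of 5 families rose, 4 when adjusted over the list alone and 1 with total-signal scaling; of the cellulose list 3 of 4 rose, 3 adjusted over the list alone and 1 with total-signal scaling.

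In NR against Control, limma called 85 families, 77 higher and 8 lower, and 158 had an unadjusted p under 0.05. Total-signal scaling called 37, with 25 higher and 12 lower, and no scaling called 12, with 2 higher and 10 lower; with the scaling factor in the model nosZ, thioredoxin and arhA were at -0.09, 0.10 and 0.03, and as a mean of log2 values mhqA was at -0.01. The family count was 26 without Control replicate 3 and 29 without NR replicate 1. Of the probes 3119 passed, 1616 higher and 1503 lower, against 1440 higher and 1996 lower with total-signal scaling, 449 and 1352 over probes detected on all 18 arrays, and 2523 and 959 with quantile normalization. A bphA probe of Pseudoalteromonas rose by 1.71 ± 0.365 and a CODH probe of Rhodospirillum rubrum by 1.54 ± 0.315, while an nplT probe of Yersinia frederiksenii fell by 2.20 ± 0.51 and a sox probe of Chlorobium limicola by 1.86 ± 0.42. Probe counts were 1471 without Control replicate 2, 1340 without Control replicate 3, and 1146, 1600 and 1508 without NR replicates 1, 2 and 3.

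For nitrogen and phosphorus with straw, a single family passed against Control. It was phdG, whose signal rose from 19.4 ± 2.02 to 38.0 ± 5.24 (units of 1000, SD, n = 3), a change of 0.97 ± 0.18 (limma adjusted p = 0.0483). The next families by p were SmtA at 0.49 ± 0.105, integrase_serine at 1.75 ± 0.39 and thmAB at 0.98 ± 0.22, each with an adjusted p of 0.0629. The values of mcrA, pmoA and the sulfite reductase gene dsrA were 0.29 ± 0.078, 0.20 ± 0.052 and 0.16 ± 0.044, each with an adjusted p of 0.076; without scaling between arrays they were -0.06, -0.15 and -0.19. An unadjusted p under 0.05 was found for 77 families. Total-signal scaling called 11 families, 10 higher and 1 lower, quantile normalization called 169, and no scaling called 247, of which 242 were lower. Leaving out Control replicate 1, 2 or 3 gave 9, 2 or 0 families, and leaving out NPR replicate 1 or 3 gave 0 or 3. At the probe level 973 passed, 779 higher and 194 lower, against 553 and 1522 without scaling. A clpC probe of Cyanothece rose by 1.59 ± 0.33 and a czcA probe of Mesorhizobium, from a metal efflux system, by 1.54 ± 0.27, while the fnr probes of Alicyclobacillus acidocaldarius and Roseobacter fell by 1.28 ± 0.205 and 1.26 ± 0.245. The probe count was 578 without Control replicate 2, 507 without Control replicate 3 and 424 without NPR replicate 1.

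Full mineral fertilization with straw was also set against Control. Of the key genes mcrA rose most, from 607 ± 17.4 to 931 ± 58.6 (units of 1000, SD, n = 3), a change of 0.61 ± 0.078 (limma adjusted p = 0.000125), and pmoA and mmoX, of methane oxidation, rose by 0.42 ± 0.052 and 0.35 ± 0.091 (adjusted p = 0.000125 and 0.00628). Relative to the median family the changes of mcrA and pmoA were 0.41 and 0.21, and with total-signal scaling 0.43 and 0.23. All 5 denitrification families passed, also when adjusted over the list alone: nosZ rose by 0.42 ± 0.080, nirS by 0.39 ± 0.052 (0.21 and 0.18 above the median family) and the nitric oxide reductase gene norB by 0.31 ± 0.057, whereas narG at 0.155 and nirK at 0.14 lay below the median family and turned to -0.03 and -0.04 with total-signal scaling. With that scaling 2 of the 5 passed. The nitrogenase gene nifH rose by 0.21 ± 0.040 with median scaling and was at 0.02 with total-signal scaling, gdh rose by 0.42 ± 0.099, and the ammonia monooxygenase gene amoA rose by 0.10 ± 0.037 with median scaling but was at -0.08 with total-signal scaling. The urease gene ureC, at 0.10 ± 0.045, did not pass (adjusted p = 0.082), and was at -0.09 with total-signal scaling. The bacterial marker gyrB rose by 0.24 ± 0.037 with median scaling and was at 0.05 with total-signal scaling. With total-signal scaling mmoX, norB, narG, nirK, nifH, gdh, amoA and gyrB did not pass (adjusted p = 0.149, 0.0508, 0.41, 0.38, 0.718, 0.0508, 0.078 and 0.234). Over probes detected on all 18 arrays nirK, nifH, amoA and gdh were at -0.06, -0.03, -0.04 and 0.17 and did not pass.

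For polymer breakdown, carbon fixation, sulfur and phosphorus in NPKR, counts of called families are given by list. Of 13 starch and hemicellulose families 10 rose, with 10 also adjusted over the list alone and 2 with total-signal scaling; xylanase rose by 0.40 ± 0.047 and glucoamylase by 0.36 ± 0.074, while amyA rose by 0.15 ± 0.038 with median scaling and was at -0.04 with total-signal scaling. In the cellulose list 3 of 4 rose, 3 adjusted over the list alone, with exoglucanase at 0.51 and cellobiase at 0.33; all 3 chitin families rose, 3 adjusted over the list alone, with endochitinase at 0.28. Pectinase rose by 0.54 ± 0.067 (adjusted p = 0.000125) and phenol_oxidase, of lignin breakdown, by 0.34 ± 0.052. All 5 carbon fixation families rose, 5 adjusted over the list alone and 2 with total-signal scaling, among them aclB, the ATP citrate lyase gene of the reductive citrate cycle, by 0.52 ± 0.060 and rubisco by 0.32 ± 0.059. All 5 sulfate and sulfite reduction families rose, 5 adjusted over the list alone and 2 with total-signal scaling, with dsrA at 0.29 and dsrB at 0.24. For phosphorus, ppk and phytase rose by 0.36 ± 0.065 and 0.36 ± 0.096, ppx was at 0.10 ± 0.052, or -0.08 with total-signal scaling, and did not pass, and 5 of 6 families of the phosphate limitation list rose, 5 adjusted over the list alone, led by the phosphate-binding gene pstS at 0.32. Phytase, dsrB and amyA did not pass with total-signal scaling (0.17, 0.05 and -0.04; adjusted p = 0.131, 0.336 and 0.292). Over probes detected on all 18 arrays phytase, dsrA, pstS and amyA were at 0.08, 0.09, 0.06 and 0.10 and did not pass (adjusted p = 0.475, 0.143, 0.331 and 0.0884). With the scaling factor in the model, nosZ, narG and phytase were at -0.02, -0.01 and -0.04.

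**Figure D4:**
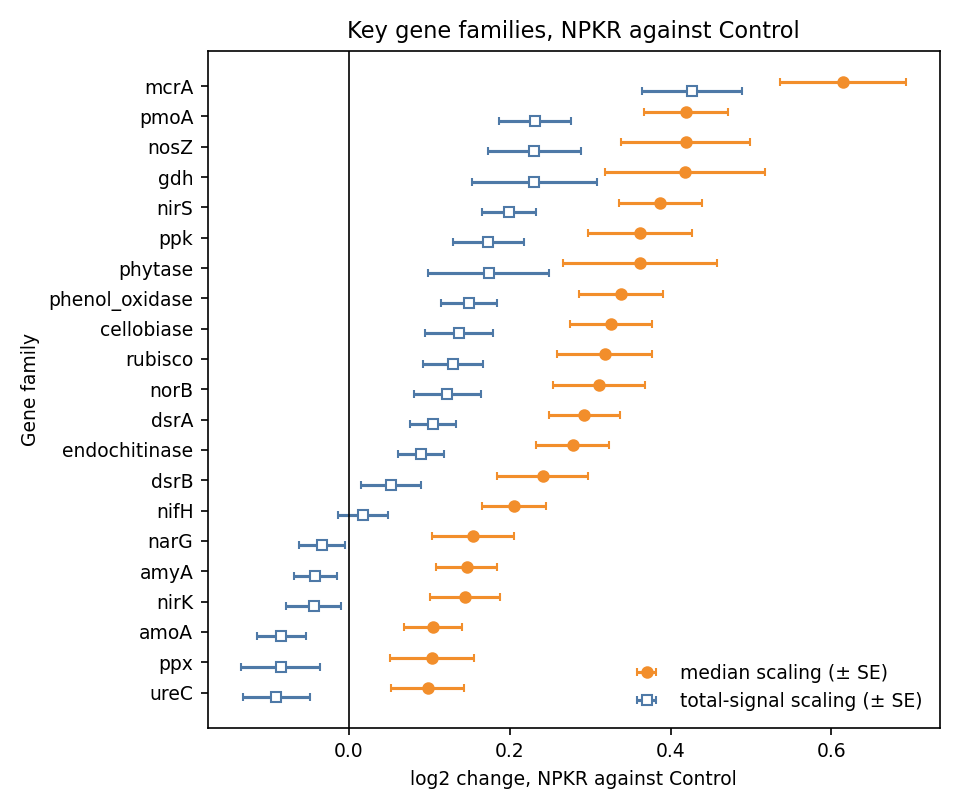
Log2 change ± SE of the key gene families in NPKR against Control with median scaling (filled circles) and total-signal scaling (open squares), 3 arrays per treatment. With median scaling mcrA was highest at 0.61 and ureC lowest at 0.10; with total-signal scaling mcrA was at 0.43, and narG, amyA, nirK, amoA, ppx and ureC lay below 0.

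In NPKR, among families with at least 5 kept probes, the phage integrase_serine rose by 2.06 ± 0.39, the single-stranded DNA-binding family ssb by 1.31 ± 0.17 (adjusted p = 0.000125), arsenic_resistance_gene by 1.30 ± 0.25 and the phage helicase_family_4 by 1.18 ± 0.17. The families phdJ and phdG rose by 1.00 and 0.93, and the T4-type phage families clamp_loader_T4_ATPase and T4_type_portal_protein by 0.84 (adjusted p = 0.145 with total-signal scaling) and 0.82. The ssb probes were detected in 36 of 48 measurements in NPKR and 16 of 48 in Control. Among the lower families of that size, arhA fell by 0.45, nagL by 0.32, arcB by 0.29 and bglH by 0.29. Over probes detected on all 18 arrays nagL was at -0.0068 and arcB at -0.01 (adjusted p = 0.978 and 0.903). The family cah fell by 0.25 but was at 0.04 with quantile normalization, and bglH was at 0.045 with the scaling factor in the model. The oxygen-limitation regulator arcA rose by 0.79 ± 0.11.

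In NPKR against Control, limma called 219 families, 209 higher and 10 lower, and 242 had an unadjusted p under 0.05. Quantile normalization called 302 higher and 4 lower, and no scaling 39 and 6. Total-signal scaling called 84, with 52 higher and 32 lower, and all of these 52 and 10 of these 32 had the same call with median scaling. None of the 210 camera tests, on 21 lists in 10 comparisons, passed with the preset correlation or with an estimated one; the lowest adjusted p was 0.146, and 22 tests had an unadjusted p under 0.05. With fry, which does not compare a list with other families, 119 passed. Of the probes 7250 passed, 4173 higher and 3077 lower, against 2801 higher and 4001 lower with total-signal scaling. With median scaling more probes were lower in other settings too: 1405 higher and 2548 lower over probes detected on all 18 arrays, 2806 and 3215 with the matched floor, and 3193 and 3395 with the floor at the fifth percentile. More were higher with quantile normalization, 8587 higher and 2220 lower, and without scaling, 3936 and 3325. A catB probe of Pedobacter rose by 2.13 ± 0.37 and a pstA probe of Desulfovibrio desulfuricans by 2.05 ± 0.35, while a BpH probe of Aspergillus clavatus fell by 2.60 ± 0.47, a cda probe of Listeria welshimeri fell by 2.27 ± 0.38 and a TehB probe of Escherichia albertii fell by 2.18 ± 0.18 (adjusted p = 1.01e-05). The probe count was 4736 without Control replicate 2, 4534 without Control replicate 3 and 4722 without NPKR replicate 3.

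At reduced rates of straw and minerals, the same comparison with Control gave mcrA at 0.54 ± 0.078 (limma adjusted p = 0.000909), from 607 ± 17.4 to 880 ± 27.2 (units of 1000, SD, n = 3), and 0.37 above the median family. The families pmoA, nirS, nosZ and gdh rose by 0.41, 0.33, 0.39 and 0.45, rubisco by 0.34 and pectinase by 0.50. Relative to the median family these 6 were at 0.24, 0.16, 0.23, 0.28, 0.17 and 0.33. Over probes detected on all 18 arrays nirS was at 0.05 and did not pass (adjusted p = 0.359), and with the scaling factor in the model nosZ was at -0.11. Of the families with at least 5 kept probes integrase_serine rose by 2.08 ± 0.39 (detected in 3 of 15 Control measurements), then arsenic_resistance_gene by 1.19, clamp_loader_T4_ATPase by 1.165, phdG by 1.16, helicase_family_4 by 1.13, ssb by 1.11, phdJ by 1.06 and thmAB by 0.98. The lowest family of that size was trzA, which fell by 0.90 with all kept probes but was 0.54 higher over its probes detected on all 18 arrays. Below 0 were also dxnA at -0.47, bglH at -0.46, thioredoxin at -0.43, arcB at -0.38, chnC at -0.30, arhA at -0.26, and xylG at -0.19, which was at 0.04 with quantile normalization. Over probes detected on all 18 arrays arcB was at -0.17 and xylG at -0.19 and did not pass (adjusted p = 0.105 and 0.0626). With the scaling factor in the model thioredoxin, arhA, xylG and chnC were at 0.36, 0.20, 0.20 and 0.10. All 5 denitrification families rose, 5 adjusted over the list alone and 3 with total-signal scaling, and 4 of 5 carbon fixation families rose, 4 adjusted over the list alone.

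In L_NPKR against Control, limma called 190 families, 175 higher and 15 lower, and 218 had an unadjusted p under 0.05. Total-signal scaling called 98, with 64 higher and 34 lower, and no scaling called 31, with 17 higher and 14 lower. The count was 110 without Control replicate 3. Of the probes 9337 passed, 5835 higher and 3502 lower, against 4478 higher and 4187 lower with total-signal scaling, 4295 and 4313 without scaling, and 1980 and 2754 over probes detected on all 18 arrays. Quantile normalization gave 12737 higher and 2314 lower. The clpC probe of Cyanothece rose by 2.45 ± 0.33, a Catechol probe of Sphingomonas wittichii by 2.33 ± 0.45 and an xylA probe of Agrobacterium tumefaciens by 2.13 ± 0.28. The nplT probe of Yersinia frederiksenii fell by 2.49 ± 0.51 and an hly probe of Desulfotomaculum reducens fell by 2.20 ± 0.225 (adjusted p = 5.22e-05). The probe count was 5344 without Control replicate 3 and 4493 without L_NPKR replicate 1.

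Adding nitrogen to straw was the step from R to NR. The denitrification gene nirS rose by 0.44 ± 0.052 (limma adjusted p = 0.000179), mcrA by 0.54 ± 0.078 and pmoA by 0.36 ± 0.052, at 0.31, 0.41 and 0.24 above the median family. Of the denitrification list 3 of 5 families rose, 3 adjusted over the list alone and 2 with total-signal scaling. Pectinase rose from 141 ± 7.58 to 231 ± 10.8 (units of 1000, SD, n = 3), a change of 0.71 ± 0.067 (limma adjusted p = 1.81e-05), rubisco rose by 0.34 ± 0.059 and phenol_oxidase by 0.28 ± 0.052. Rubisco and phenol_oxidase were at 0.16 and 0.07 over probes detected on all 18 arrays and did not pass (adjusted p = 0.0748 and 0.201). The largest increases in families with at least 5 kept probes were in arsenic_resistance_gene at 1.72 ± 0.25, integrase_serine at 1.53, the lead transporter family pbrT at 1.24, helicase_family_4 at 0.90 and BDO at 0.90. Of that size, the vancomycin resistance family Van fell by 1.24, thioredoxin by 0.71, the peroxide regulator perR by 0.49, arhA by 0.45 and endolysin_transglycosylase by 0.40, which was at -0.05 over probes detected on all 18 arrays. In total 144 families passed, 123 higher and 21 lower, and 201 had an unadjusted p under 0.05. Total-signal scaling called 117, with 65 higher and 52 lower, no scaling 38, with 17 and 21, and quantile normalization 308, with 297 and 11. The count was 66 without R replicate 2 and 85 without NR replicate 1. With the scaling factor in the model pbrT, BDO, thioredoxin, arhA and perR were at -0.11, -0.12, 0.09, 0.01 and 0.27.

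For phosphorus added to nitrogen and straw, NPR against NR, no family passed. The families with the smallest p were nicdehydr at -0.43 ± 0.095, phytase at -0.38 ± 0.096, nitro at -0.29 ± 0.075 and xylanase at -0.19 ± 0.047, each with an adjusted p of 0.188, and mcrA was at -0.15 ± 0.078. Limma called 0 of 416 families, 54 had an unadjusted p under 0.05, and total-signal scaling also gave 0, with 49. No scaling gave 14 families, all lower in NPR, and 1 family passed without NR replicate 1 and 1 without NPR replicate 2.

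For potassium added to nitrogen, phosphorus and straw, NPKR against NPR, the phage family ssb rose most among families with at least 5 kept probes, by 0.86 ± 0.17 (limma adjusted p = 0.00706), arcA by 0.59 ± 0.11, RNA_dependent__RNA_polymerase by 0.59, nicdehydr by 0.53 and the copper-binding family CusF by 0.53. Phytase rose by 0.49 ± 0.096, mcrA by 0.33 ± 0.078, nirS by 0.26 ± 0.052 and pmoA by 0.22 ± 0.052. Relative to the median family these 4 were at 0.34, 0.18, 0.11 and 0.07. The values were 0.35, 0.18, 0.11 and 0.07 with total-signal scaling, and none of them passed there; over probes detected on all 18 arrays phytase was at 0.15 and did not pass (adjusted p = 0.186). The count was 123 families, 122 higher and 1 lower, with 180 at an unadjusted p under 0.05. The 1 lower family, sulfur_reductase, at -0.54 over 3 probes, was named after its value was seen. Total-signal scaling called 0, with 81 at an unadjusted p under 0.05. The count was 31 without NPKR replicate 2, 54 without NPKR replicate 1, 68 without NPR replicate 2 and 36 without NPR replicate 3.

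Between reduced and full rates, L_NPKR against NPKR, no family passed. The smallest p belonged to trzA at -0.785 ± 0.29, the carbon fixation family aclB at -0.20 ± 0.060, xylanase at -0.13 ± 0.047 and pstS at -0.12 ± 0.042, each with an adjusted p of 0.853, and mcrA was at -0.08 ± 0.078. Limma called 0 of 416 families, 19 had an unadjusted p under 0.05, and total-signal scaling also gave 0, with 16.

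A last contrast set the mean of the 3 treatments with phosphorus (NPR, NPKR and L_NPKR) against the mean of the 3 without it (Control, R and NR). In it mcrA rose by 0.37 ± 0.045 (limma adjusted p = 9.05e-05), pmoA by 0.25 ± 0.030 and nirS by 0.23 ± 0.030, at 0.26, 0.14 and 0.12 above the median family; over probes detected on all 18 arrays nirS was at 0.05 (adjusted p = 0.185). Counting families with at least 5 kept probes, the largest increases were in integrase_serine at 1.02, arsenic_resistance_gene at 0.98, clamp_loader_T4_ATPase at 0.94, ssb at 0.77, phdJ at 0.70, helicase_family_4 at 0.68, mercury_resistant_gene at 0.67 and thmAB at 0.66. The family trzA fell by 0.48 with all kept probes and was 0.27 higher over probes detected on all 18 arrays; arhA fell by 0.26, dxnA by 0.25, bglH by 0.24, arcB by 0.20 (-0.13 over probes detected on all 18 arrays, adjusted p = 0.0544), and xylC by 0.10, which was at 0.08 with quantile normalization and 0.14 as a mean of log2 values. With the scaling factor in the model 1 family passed, and arhA and trzA were at 0.03 and 0.07. Limma called 201 families, 190 higher and 11 lower, and 228 had an unadjusted p under 0.05; total-signal scaling called 122, with 78 higher and 44 lower, and no scaling 39, with 23 and 16. Of the probes 11362 passed, 7354 higher and 4008 lower, against 5350 higher and 4757 lower with total-signal scaling and 2163 and 3084 over probes detected on all 18 arrays. Quantile normalization gave 17073 higher and 2415 lower. The contrast also differs in the other nutrients and in array brightness, since only treatments without phosphorus include Control and R.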

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

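The floor matched to the dimmest array, the scaling factor as a covariate and total-signal scaling of the lists, with either correlation, were tests chosen only after the result was seen; the others were planned. The differences between treatments in detected probes, Shannon index and composition passed their permutation tests under every alternative tried for them. The shares with all 18 arrays were 93.95% to 94.55%, 94.15% to 94.44% and 49.72% (Euclidean distances) to 60.81% (Jaccard distances). The matched floor was tried for detected probes, but not for the Shannon index or composition. A part of their differences that comes from detection was therefore not tested.

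Total-signal scaling gave 37 families in NR, 11 in NPR, 84 in NPKR and 98 in L_NPKR against Control, 0 in NPKR against NPR (limma, 81 at an unadjusted p under 0.05), 122 in the phosphorus contrast, and 5 camera tests of lists, all of antibiotic resistance, of which 0 passed with an estimated correlation as well. In NPKR it put nirK at -0.0436, narG at -0.0333, amoA at -0.0834 and amyA at -0.0417. Quantile normalization gave 2 families in R, 222 in NR, 169 in NPR and 315 in L_NPKR against Control, 308 in NR against R, 60 in NPKR against NPR and 349 in the phosphorus contrast, and 1914, 15051 and 19488 probes in NPR, L_NPKR and the phosphorus contrast. It put cah at 0.0439 in NPKR, xylG at 0.0406 in L_NPKR and xylC at 0.0773 in the phosphorus contrast. No scaling gave 12 families in NR (2 higher, 10 lower), 247 in NPR (5 higher, 242 lower), 45 in NPKR (39 higher, 6 lower) and 31 in L_NPKR against Control, 38 in NR against R, 14 in NPR against NR, 298 in NPKR against NPR and 39 in the phosphorus contrast, 278 and 2075 probes in R and NPR, and dsrA at -0.19 in NPR.

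With the scaling factor as a covariate limma called 0 families in NR, NPR, NPKR and L_NPKR against Control, where 25, 41, 68 and 47 had an unadjusted p under 0.05, and 2 in NR against R, 1 in NPKR against NPR and 1 in the phosphorus contrast. It called 26, 105, 31 and 26 probes in NR, NPR, NPKR and L_NPKR and 28 in the phosphorus contrast. Under it thioredoxin, arhA and nosZ were at 0.0958, 0.0275 and -0.0917 in NR, and bglH, nosZ, narG and phytase at 0.045, -0.0192, -0.0104 and -0.0387 in NPKR. In L_NPKR chnC, thioredoxin, arhA, xylG and nosZ were at 0.0976, 0.362, 0.202, 0.196 and -0.113. In NR against R pbrT, BDO, thioredoxin, arhA and perR were at -0.108, -0.124, 0.0872, 0.011 and 0.267, and in the phosphorus contrast arhA and trzA were at 0.03 and 0.0697.

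With probes detected on all 18 arrays alone, 28 families passed in NR, 3 in NPR, 115 in NPKR (98 higher, 17 lower) and 79 in L_NPKR against Control, 78 in NR against R (39 higher, 39 lower), 54 in NPKR against NPR and 70 in the phosphorus contrast. The probe counts were 0 in R (limma, 1700 at an unadjusted p under 0.05), 1801 in NR (449 higher, 1352 lower), 257 in NPR (152 higher, 105 lower), 3953 in NPKR (1405 higher, 2548 lower), 4734 in L_NPKR (1980 higher, 2754 lower) and 5247 in the phosphorus contrast (2163 higher, 3084 lower). In NPKR nirK, nifH and amoA were at -0.0633, -0.0282 and -0.0385, and trzA was at 0.543 in L_NPKR and 0.274 in the phosphorus contrast. The mean of log2 values gave 200 families in NR, 76 in NPR and 263 in NR against R, with mhqA at -0.0135 in NR and xylC at 0.144 in the phosphorus contrast. The floor at the fifth percentile gave 95 probes in R, and the matched floor 0 families in NPR, 38 probes in R and 557 in NPR. Probes detected on at least 1 array gave 0 families in NPR, families with at least 1 kept probe 0 in NPR and 1 in NPR against NR, and trend with robust settings 8 in NPR. With only the compared groups in the fit, 47 families passed in NR, 0 in NPR, 115 in NPKR and 53 in NR against R, with 38 probes in R and 499 in NPR. Where limma called 0 families in NPR, an unadjusted p under 0.05 was found for 66 with the matched floor, 79 with probes detected on at least 1 array, 94 with families of at least 1 probe and 58 with only the compared groups.

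The replicate number as a block gave 3 families in NPR and changed no other count of calls by over 1.5 times; among the named families 2 no longer passed and 1 newly passed. Deviations of arrays with the same number had a mean correlation of 0.0074 (-0.30 to 0.30), against -0.0037 for arrays with other numbers. Of the 45 pairs with the same number 13 were over 0.1, and 9 of 18 arrays correlated best with their own number. The deviations were taken from treatment means, which holds both mean correlations near 0. These values therefore do not settle whether the numbers pair the arrays.

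Leaving out 1 array at a time gave 0 to 5 families in R, 26 to 72 in NR, 0 to 9 in NPR, 159 to 204 in NPKR and 110 to 168 in L_NPKR against Control. It gave 66 to 182 in NR against R, 0 to 1 in NPR against NR, 31 to 140 in NPKR against NPR, 0 to 0 in L_NPKR against NPKR and 158 to 211 in the phosphorus contrast. The probe counts were 197 to 1557 in R, 1146 to 2356 in NR, 424 to 1240 in NPR, 4534 to 6720 in NPKR, 4493 to 9180 in L_NPKR and 8700 to 12746 in the phosphorus contrast. The lowest counts came without Control replicate 3 in NR (26), NPKR (159) and L_NPKR (110), without R replicate 2 in NR against R (66) and without NPKR replicate 2 in NPKR against NPR (31); the highest in R (5 families, 1557 probes) came without R replicate 1. Detected probes, Shannon index and composition had shares of 93.28% to 95.77%, 93.43% to 96.61% and 55.16% to 60.41%.

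For the named families, a change of sign was counted only where the value passed in the main or the other setting. Values that passed in neither were counted as staying, whatever their sign. Of the 159 values of named families, total-signal scaling left 127 on the same side of the test. A further 24 no longer passed but kept their sign, 4 newly passed and 4 changed sign. The counts were 129, 18, 9 and 3 with quantile normalization, 96, 57, 5 and 1 without scaling, 127, 23, 7 and 2 with the mean of log2 values, and 24, 116, 0 and 19 with the covariate. Of 1158 values with 1 array left out, 1059 stayed, 95 no longer passed, 4 newly passed and 0 changed sign by this count.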

Other observations

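Families of stress and resistance lists are given here for NPKR against Control, where 209 of all 416 families were called higher, 52 with total-signal scaling. For oxidative stress 6 of 7 families were called higher, 6 adjusted over the list alone and 0 with total-signal scaling, with katA at 0.28; for heat and cold shock 5 of 11, 5 and 0, with groEL at 0.29. For osmotic stress 2 of 4 were higher, 2 and 1, with proX at 0.70; for electron transfer 4 of 5, 5 and 1, with cytochrome_bd at 0.57. The arsenic list had 3 of 5 higher, 3 adjusted over the list alone and 2 with total-signal scaling, with ArsA at 0.59 and arsB at 0.435. The list of copper, zinc, cadmium and chromium resistance had 7 of 10 higher, 7 and 1, with czcD at 0.40, and mercury resistance 3 of 5, 3 and 1, with merT at 0.62. Oxygen limitation was mixed, with 4 of 7 higher and 1 lower, where arcA was at 0.79 and arcB at -0.29, or -0.01 over probes detected on all 18 arrays. With total-signal scaling katA, groEL and cytochrome_bd did not pass (adjusted p = 0.178, 0.163 and 0.0514). Over probes detected on all 18 arrays katA, groEL, arsB and merT did not pass (adjusted p = 0.101, 0.0509, 0.0787 and 0.189).

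The median change of antibiotic resistance families in NPKR was 0.0798 with median scaling and -0.108 with total-signal scaling, against 0.207 and 0.019 for all families. With median scaling 3 of 11 were higher and 1 lower, with 2 higher and 1 lower adjusted over the list alone, SMR_antibiotics at 0.22 (adjusted p = 0.474 with total-signal scaling) and B_lactamase_B at -0.61. With total-signal scaling 0 were higher and 4 lower. With that scaling the list was lower in camera in NPKR against Control at the preset correlation (adjusted p = 0.00337), and at an estimated correlation it did not pass (adjusted p = 0.0862). With median scaling its adjusted p was 0.156 at the preset and 0.675 at the estimated correlation. The list tests with total-signal scaling were chosen after seeing the data.

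For the patterns below, the tests of detected probes and of the mostly higher calls were chosen only after the result was seen. More probes were detected in the 4 treatments with nitrogen, whose arrays were also brighter as judged by the factor. Within treatments, detected probes rose by 2760 ± 1710 per doubling of brightness (r = 0.438, exact p = 0.207 over 46656 permutations), against 7770 between treatments, so brightness at the slope seen within treatments falls short of the whole difference. A lower detection limit in signal on bright arrays fits as a part of the cause: 1 floor for every array took 4033 ± 604 (SE) probes from the excess of NPKR over Control. The 5251 ± 658 that were left argue against a sharp limit at that floor as the whole cause. A limit that also hides probes above that floor on dim arrays was not tested and stays open. The detection rule is not given in the sources used here, so a limit set by noise stays open, and so does an effect of fertilization on the richness of functional genes, which may explain the rest.

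Most called families were higher in NPKR, 95.4% with median scaling. It was 86.7% without scaling between arrays (39 higher, 6 lower), where the listed intensities kept their factor per array. With quantile normalization it was 98.7% (302 higher, 4 lower). That method gave the listed values of all arrays 1 distribution and left blanks at 0 in the family sums. An array with more detected probes then tends to higher sums by construction, so this split decides nothing. Blanks also counted as 0 in the sums with median scaling and without scaling, so detection enters those splits as well. Over probes detected on all 18 arrays, which have no blanks, 98 families were higher and 17 lower in NPKR. In NR against R 39 were higher and 39 lower over those probes, against 123 and 21 with all kept probes. Without scaling most calls were lower in NR (2 higher, 10 lower) and NPR (5 higher, 242 lower) against Control. Equal totals centre the family sums near 0 by construction, so the 52 higher and 32 lower with total-signal scaling decide nothing, and the choice of scaling stays open as a cause. The median family value of each array differed between NPKR and Control by a mean of 0.202 ± 0.0282 (the median of the changes of single families was 0.207), and by 0.0868 ± 0.0449 with the scaling factor in the model, which fits array brightness as a part of it. Since treatments held 91.2% of the variance of the factor, that model can also remove real differences that go with treatment. Also open is the order of families: mcrA, at 0.61 with median scaling and 0.43 with total-signal scaling, lay above the median family under both. A higher share of methanogens with fertilization is a candidate explanation that was not tested. The mcrA probes were detected in 59.8% of measurements in Control and 90.5% in NPKR, and a part played by weak detection was not tested for mcrA.

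Among 36 phage families 15 were called higher and 1 lower in NPKR, and 7 and 2 with total-signal scaling. Of all 416 families 209 were called higher and 10 lower, and 52 and 32 with total-signal scaling. The median change of the phage families, 0.296, was set against 10000 random sets of other families with similar numbers of probes and similar detection in Control. It lay at percentile 37.3 of these sets, whose median was 0.307 (0.164 to 0.450). Weak detection could therefore explain the size of the phage changes: the median share of a family's measurements detected in Control was 58.3% for phage families and 71.4% for other families. The mean difference of the phage families was 0.427 ± 0.0504, and 0.451 ± 0.107 with the scaling factor in the model. Brightness at its slope within treatments thus falls short of that mean, which families near the floor, such as integrase_serine, can carry. The median change was not tested in this way. Weak detection goes with dim arrays, so array brightness as a cause stays open. More phage DNA with fertilization stays open, and ssb and integrase_serine, at 1.31 and 2.06 with few detections in Control, are where it would be sought first.

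The phosphorus contrast, with 201 families, was compared with the other ways to put the 6 treatments into 3 and 3, a test written before the result. Of the 10 groupings 2 gave as many families, the real one included. NR, NPKR and L_NPKR against Control, R and NPR gave 283, with a difference in log2 brightness of 1.04 against 0.822, and the next gave 107. The contrast may therefore reflect nutrients other than phosphorus, or brightness.

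Other splits of the same arrays were counted for each comparison. In the phosphorus contrast 1 of 100 splits gave as many families, the real one with 201, against 1 family at most in the others. For probes 1 of 100 gave as many, 11362 against 60. The other splits mix arrays of different treatments within a group, so treatment differences enter their residual spread and lower their counts. They show that arrays of a treatment resemble each other, which a shared brightness could also give, and do not exclude chance. With whole treatments as the unit, 2 of the 10 groupings gave as many families. The comparisons of 3 arrays with 3 have 10 splits, too few for a share under 0.05. Their other splits also mix arrays of both treatments within a group. For families the real and the highest other count were 85 and 0 in NR, 1 and 0 in NPR, 219 and 0 in NPKR, 190 and 0 in L_NPKR against Control, 144 and 1 in NR against R and 123 and 0 in NPKR against NPR, with 1 split of 10 reaching the real count in each. In R against Control, NPR against NR and L_NPKR against NPKR the real count was 0, which 10 of 10 splits reach, and the highest other was 0, 1 and 0. For these 3, limma gave 40, 54 and 19 families at an unadjusted p under 0.05. For probes the counts were 3119 and 26 in NR, 973 and 24 in NPR, 7250 and 13 in NPKR and 9337 and 7 in L_NPKR against Control. In R against Control 3 of 10 splits gave at least the real 157 probes and the highest gave 434, so the real split was not the one with the most calls. The cause was not tested, and without R replicate 1 the count was 1557.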
